A study of Mus musculus with 11 samples.

How the data were processed

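Total RNA of 11 libraries of mouse primary myoblasts was sequenced after 6 h at 21% or 1% oxygen. The cells came from the tibialis anterior and grew in Ham's F-10 medium with 20% fetal bovine serum and 2.5 ng/ml basic fibroblast growth factor. Libraries were made from 1 µg of RNA with a stranded total RNA kit. The processing notes of the submitters name bcl2fastq, STAR, Picard, HTSeq, RSEM and DESeq2 and the mm10 build, without versions and without saying which of the counting tools made the table. The values deposited by the authors are signal, read counts divided by 1 size factor per library, for 22104 Ensembl gene identifiers, and 0 columns were left unused. Multiplying each library by its size factor gave whole reads for 100% of values within 0.01 read. Each listed gene had at least 2 reads over all libraries. A symbol was found for 21805 identifiers and not for 299. Gene positions and types came from the GENCODE M21 annotation of GRCm38.

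Recovered reads per library totalled 18707697 to 33613328, and 18496 to 19406 genes had reads. At this depth the median SE of a log2 change was 0.11 in wild-type hypoxia and in the normoxia genotype comparison, 0.10 in knockout hypoxia and in the hypoxia genotype comparison, and 0.15 for the difference between the hypoxia effects. For pairs of libraries of the same group, the chi-square over its degrees of freedom was 4.84 to 24.5, above the value of 1 that counting error alone would give. No library was therefore a duplicate of another in its group, and pairs across groups were not compared. Reads that map to a gene and its pseudogene, or to overlapping genes, were assigned by the authors' tools in a way that the values do not show.

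Values were log2-transformed after adding a pseudocount of 1, a scale that understates the change of genes with low counts. Genes with a value of at least 10 in at least 2 libraries were tested, 14729 in all. A linear model with 4 groups was fitted with limma 3.58.1 in R 4.3.3, with a trend of variance on mean expression (residual degrees of freedom 7, prior 6.35). It gave 5 two-sided comparisons, which were hypoxia against normoxia in each genotype, knockout against wild-type at each oxygen level, and the difference between the hypoxia effects of the genotypes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes in each comparison, and a gene was called at an adjusted p under 0.05. Rose and fell are used for called genes. No pairing of libraries was used because the labels give no link between replicates of different groups. Whether such a link exists is not known, and no fit with a pairing was run.

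Gene lists, comparisons, the naming rule and the alternatives were written before the data were examined, except where stated. There were 31 lists. They held glycolysis, HIF targets outside glycolysis, oxygen sensing and HIF subunits, clock repressors and E-box outputs, clock activators and RORE outputs, NAD metabolism, satellite cell and myoblast identity, and muscle differentiation. They also held nuclear-encoded respiratory chain, mitochondrially encoded transcripts, pyruvate dehydrogenase and TCA cycle, mitosis, DNA replication, integrated stress response, ER chaperones and unfolded protein response, and NRF2 and pentose phosphate genes. The remaining process lists were cholesterol synthesis, extracellular matrix, inflammatory cytokines and chemokines, interferon response, p53 targets, cytosolic ribosomal proteins and immediate early genes. Marker lists covered fibro-adipogenic progenitors and fibroblasts, endothelial cells, leukocytes, pericytes and smooth muscle, Schwann cells and adipocytes, and check lists covered sex-linked transcripts and chromosome 7 neighbours of Arntl. Of these, 27 were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. The leukocyte and adipocyte markers had fewer than 5 tested members, and the check lists were counted only. Lox is in the lists of HIF targets and of fibroblasts, and 1 other shared member is not reported here. Zbed5, placed among the chromosome 7 neighbours, is annotated on chromosome 5.

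Genes were named by rule. Arntl was always named, as were Hif1a, Vegfa, Slc2a1, Ldha, Pdk1, Nampt, Per2, Nr1d1, Dbp, Myod1, Pax7 and Myog. In each comparison up to 10 risen and 10 fallen genes with the largest log2 change were added, among called genes with a mean of at least 50 in the higher group, no overlap between the groups and no symbol of a predicted model, clone or pseudogene. Up to 4 members of each list with the smallest adjusted p were added too. The hypoxia response of the genotypes was compared with 3 scores, each the mean log2 value over a set of genes, in an exact permutation test with 200 arrangements of genotype labels within oxygen levels.

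The fit was tested on simulated data with 200 genes shifted in 1 group. They were drawn from genes with a mean of at least 50, so recovery of lower genes was not measured. Recovery where fewer genes change, which makes the adjusted p harder to pass, was not measured either. With a shift in knockout hypoxia, limma recovered 79.1%, 98.5% and 100% of genes shifted by 0.5, 1 and 2 on the log2 scale for the hypoxia effect, 77.6%, 100% and 100% for the genotype effect and 41.8%, 88.1% and 98.5% for the difference of hypoxia effects. With a shift in wild-type normoxia the values were 67.2%, 98.5% and 100%, 68.7%, 94.0% and 100%, and 37.3%, 82.1% and 98.5%. Between 0 and 15 unshifted genes were called in a comparison.

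Alternatives covered the pseudocount (0.5 and 10), the filter, a fit on only the groups compared, the variance trend, robust variance, TMM and quantile scaling, a fold limit, an estimated correlation and fry for lists, medians for scores, a threshold of 0.01 for overlaps, and leaving out each library. The edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 were run on the recovered reads. For the difference between the hypoxia effects edgeR called 0 genes and DESeq2 called 4. Added after the data were seen were counts without pseudogenes and genes within 10 Mb of Arntl, a list of histone genes, and reads thinned to the smallest library. Python 3.11.15 and matplotlib 3.10.9 drew the figures.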

Results

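RNA sequencing profiled primary myoblasts, the proliferating precursor cells of skeletal muscle, grown from the tibialis anterior of C57BL/6 mice about 8 weeks old. Donor mice were wild-type or lacked Bmal1. Bmal1, listed under its gene symbol Arntl, encodes a transcription factor that pairs with CLOCK to drive the circadian clock. Cultures were kept for 6 h at 21% oxygen (normoxia) or 1% oxygen (hypoxia) before total RNA was taken. The 11 libraries comprised 2 of wild-type cells in normoxia and 3 each of wild-type cells in hypoxia, knockout cells in normoxia and knockout cells in hypoxia. Reads assigned to genes numbered 21451760 and 19668258 in the wild-type normoxia libraries and 18937827, 18707697 and 21138175 in the knockout normoxia libraries. They numbered 24587342, 33613328 and 30112840 in wild-type hypoxia and 24629657, 25731223 and 23027613 in knockout hypoxia, so each hypoxia library was deeper than each normoxia library. The mitochondrial ribosomal RNA mt-Rnr2 took 19.4 to 21.6% of the reads of a library. Over the 14729 genes tested, the correlation between libraries of the same group was 0.985 to 0.991 on the log2 scale, a value across genes, which are not independent replicates. The first principal component, 27.5% of the variance, separated the genotypes and the second, 14.3%, separated the oxygen levels. The labels do not say whether libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

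Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126 in GRCm38, protein-coding) was lower in each of the 6 knockout libraries than in each of the 5 wild-type libraries. Its normalized read count was 264 and 267 in wild-type normoxia and 325, 328 and 322 in wild-type hypoxia. The knockout libraries held 109, 117 and 98.8 in normoxia and 128, 134 and 128 in hypoxia. The log2 difference between genotypes was -1.29 (SE 0.10, adjusted p = 2.24e-06) in normoxia and -1.31 (SE 0.09, adjusted p = 4.96e-07) in hypoxia. Reads on Arntl therefore remained in the knockout cells, and the labels do not say which part of the gene was deleted, so this gene checks the genotype labels only in part. Arntl did not pass the test for hypoxia in wild-type cells (log2 difference 0.29, adjusted p = 0.207) or in knockout cells (0.26, adjusted p = 0.135).

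The comparison of wild-type cells at both oxygen levels asked which transcripts respond to 6 h of low oxygen. Genes known as targets of the hypoxia-inducible factors (HIF) were among those that rose by the largest amounts. Adm (chromosome 7, 110627661 to 110629820), which encodes the vasodilator peptide adrenomedullin, went from 59.7 ± 1.14 (SD, n = 2) to 615 ± 94.5 (SD, n = 3) normalized counts, 10.1-fold higher. Bnip3, a mitophagy receptor, went from 1127 ± 65.3 (SD, n = 2) to 8214 ± 1510 (SD, n = 3), 7.21-fold higher. Pfkfb3, which makes the activator of phosphofructokinase, went from 161 ± 10.7 (SD, n = 2) to 982 ± 96.2 (SD, n = 3), 6.07-fold higher. The keratin gene Krt19 rose by 3.53 on the log2 scale (SE 0.45). Of the genes named here the largest falls were in Txnip, an inhibitor of glucose uptake, from 1068 ± 109 (SD, n = 2) to 301 ± 22.9 (SD, n = 3), and in Tfrc, the transferrin receptor, from 3413 ± 242 (SD, n = 2) to 1489 ± 145 (SD, n = 3).

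Of the 21 glycolysis genes, 17 rose in wild-type hypoxia, 0 fell and 4 did not pass, with 17 risen when adjusted over the list alone. The median log2 change of the list was 0.77. Slc16a3, which exports lactate, rose by 1.79 (SE 0.09), the glucose transporter Slc2a1 by 1.95 (SE 0.10), the liver-type phosphofructokinase Pfkl by 1.25 (SE 0.06) and lactate dehydrogenase Ldha by 0.77 (SE 0.05). HIF targets outside glycolysis rose in 28 of 32 cases and fell in 0, with 30 risen when adjusted over the list alone and a median of 1.31. Examples were the histone demethylase Kdm3a at 1.32 (SE 0.06), the mitochondrial adenylate kinase Ak4 at 2.16, the pyruvate dehydrogenase kinase Pdk1 at 1.97 (SE 0.12) and the angiogenic factor Vegfa at 0.86 (SE 0.07). Among the 9 tested genes of oxygen sensing and HIF subunits, 3 rose and 0 fell, with 3 risen when adjusted over the list alone. These were the prolyl hydroxylases Egln1 (1.38) and Egln3 (2.45), which mark HIF for degradation, and Vhl (0.63), whose call was lost without wild-type normoxia replicate 1 or 2 or wild-type hypoxia replicate 2 (adjusted p = 0.0555 to 0.187). Hif1a itself did not pass (0.04, SE 0.06, adjusted p = 0.836). The camera test gave adjusted p = 5.69e-47 for glycolysis, 5.17e-69 for the HIF targets and 0.00129 for oxygen sensing, and 0.0148, 0.0083 and 0.041 in that order with an estimated correlation.

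Targets of the tumour suppressor p53 stood lower as a group in wild-type hypoxia. Of 21 members 0 rose and 2 fell, with 11 fallen when adjusted over the list alone, and 19 of the 21 had a negative change (median -0.21, camera adjusted p = 1.83e-08, and adjusted p = 0.0083 with an estimated correlation). The fallen members were Trp53inp1, a stress-induced partner of p53 (-0.49), and Eda2r, a receptor of the tumour necrosis factor family (-0.31). The call of Trp53inp1 was lost without wild-type normoxia replicate 2 (adjusted p = 0.0914), and that of Eda2r without either wild-type normoxia library (adjusted p = 0.053 to 0.075). Immediate early genes, which respond to growth and stress signals within minutes, had 7 risen and 0 fallen of 18, with 7 risen when adjusted over the list alone. Among them was Ier3 at 1.63 (SE 0.10), and the camera adjusted p of the list was 0.00216, with adjusted p = 0.302 with an estimated correlation. Of the 13 transcripts encoded by mitochondrial DNA, 0 rose and 3 fell, with 2 risen and 5 fallen when adjusted over the list alone, among them mt-Atp8 at -0.54 (SE 0.08), a subunit of ATP synthase. The camera adjusted p was 0.00308, and adjusted p = 0.33 with an estimated correlation. Of the clock genes, the repressors Bhlhe40 (1.83, SE 0.13) and Ciart (1.86, SE 0.17) and the activator Rora (0.96, SE 0.15) rose, while Per2 (-0.06, adjusted p = 0.913) and Nr1d1 (-0.35, adjusted p = 0.543) did not pass. Nampt, the rate-limiting enzyme of NAD salvage, rose by 0.89 (SE 0.10). The myogenic factors Myod1 (-0.17, adjusted p = 0.208), Pax7 (0.12, adjusted p = 0.673) and Myog (-0.29, adjusted p = 0.186) did not pass.

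In the limma fit, 251 genes rose and 69 fell in wild-type hypoxia, of 14729 tested at a Benjamini-Hochberg adjusted p under 0.05. Of these 74 rose and 7 fell by at least 2-fold. Without wild-type normoxia replicate 1 the counts were 153 and 34, without replicate 2 they were 143 and 18, and without wild-type hypoxia replicate 2 the count fallen was 36. Lars2, a mitochondrial leucyl-tRNA synthetase, had a wide spread between libraries, 84168 ± 36400 (SD, n = 3) against 14214 ± 3200 (SD, n = 2), and its call (adjusted p = 0.0217) was lost without any 1 of 4 libraries (adjusted p = 0.0714 to 0.205), wild-type normoxia replicates 1 and 2 and wild-type hypoxia replicates 2 and 3.

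In Bmal1 knockout cells the same comparison asked which transcripts respond to low oxygen when the clock factor is absent. Adm rose from 71.2 ± 7.46 (SD, n = 3) to 621 ± 63.9 (SD, n = 3) normalized counts, 8.62-fold, and Bnip3 from 1457 ± 110 (SD, n = 3) to 8381 ± 1250 (SD, n = 3), 5.72-fold. Bhlhe40, a HIF-responsive repressor of the clock, rose from 116 ± 4.09 (SD, n = 3) to 628 ± 111 (SD, n = 3), and the clock repressor Ciart from 60.9 ± 8.5 (SD, n = 3) to 321 ± 39.3 (SD, n = 3). Txnip fell from 647 ± 53 (SD, n = 3) to 213 ± 43 (SD, n = 3), and Tfrc from 3900 ± 113 (SD, n = 3) to 1973 ± 240 (SD, n = 3). The carbonic anhydrase Car9 rose by 2.77 on the log2 scale (SE 0.30) and the scaffold protein gene Mpp2 by 2.93 (SE 0.31).

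Glycolysis genes had 17 risen and 0 fallen of 21 in knockout hypoxia (18 risen when adjusted over the list alone, median 0.68), and HIF targets outside glycolysis 29 risen and 0 fallen of 32 (31 risen when adjusted over the list alone, median 1.09). The camera adjusted p was 1.16e-42 and 5.83e-61, and 0.0194 and 0.012 with an estimated correlation. Slc2a1 rose by 1.86 (SE 0.09), Pdk1 by 1.90 (SE 0.11), Vegfa by 0.87 (SE 0.06) and Ldha by 0.66 (SE 0.04). For p53 targets 0 rose and 8 fell, with 12 fallen when adjusted over the list alone (median -0.24, camera adjusted p = 3.05e-10, and adjusted p = 0.00653 with an estimated correlation). They included Trp53inp1 (-0.66, SE 0.07), Eda2r (-0.40) and Btg2 (-0.41), an antiproliferative gene. Among the 9 oxygen sensing genes 2 rose, Egln1 (1.30) and Egln3 (2.38), and 0 fell, with 2 risen when adjusted over the list alone. The list's median was -0.003 and its mean 0.40, the camera test called it upward (adjusted p = 0.0234), and adjusted p = 0.174 with an estimated correlation. Immediate early genes had 7 risen and 0 fallen of 18, with 9 risen and 1 fallen when adjusted over the list alone, Ier3 again among them at 1.56 (SE 0.09). Their camera adjusted p was 6.13e-05, and adjusted p = 0.192 with an estimated correlation. Clock repressors and E-box outputs, the genes that CLOCK and BMAL1 bind, had 3 risen and 0 fallen of 14 (5 risen and 1 fallen when adjusted over the list alone, camera adjusted p = 0.00197, and adjusted p = 0.213 with an estimated correlation). Transcripts encoded by mitochondrial DNA had 0 risen and 4 fallen of 13, with 5 fallen when adjusted over the list alone, such as mt-Atp8 (-0.63, SE 0.07) and mt-Nd1 (-0.43, SE 0.06). Their camera adjusted p was 0.000386, and adjusted p = 0.213 with an estimated correlation.

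Extracellular matrix genes, which build the scaffold around cells, had 5 risen and 1 fallen of 30 in knockout hypoxia (8 and 2 when adjusted over the list alone, median 0.11). Among them Loxl2, which cross-links collagen, rose by 0.45 (SE 0.08). The list's camera adjusted p was 0.0193, and adjusted p = 0.463 with an estimated correlation. Its call was lost without knockout normoxia replicate 1 or 2 or knockout hypoxia replicate 2, with adjusted p = 0.0529 to 0.0587. Fibroblast markers rose in 2 of 10 cases, Cd34 (0.50) and Lox (0.36, SE 0.04), of which Lox is also in the HIF list. That list's camera adjusted p was 0.0172, and adjusted p = 0.159 with an estimated correlation, and the call was lost without knockout normoxia replicate 2 (0.0568) or knockout hypoxia replicate 1 (0.0771). In all, 464 genes rose and 138 fell in the limma fit, 84 and 6 of them by at least 2-fold. The count risen was 304 without knockout normoxia replicate 1 and 303 without knockout hypoxia replicate 3. The count fallen was 66 and 68 without knockout normoxia replicates 1 and 2, and 76, 64 and 69 without knockout hypoxia replicates 1, 2 and 3.

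**Figure D1:**
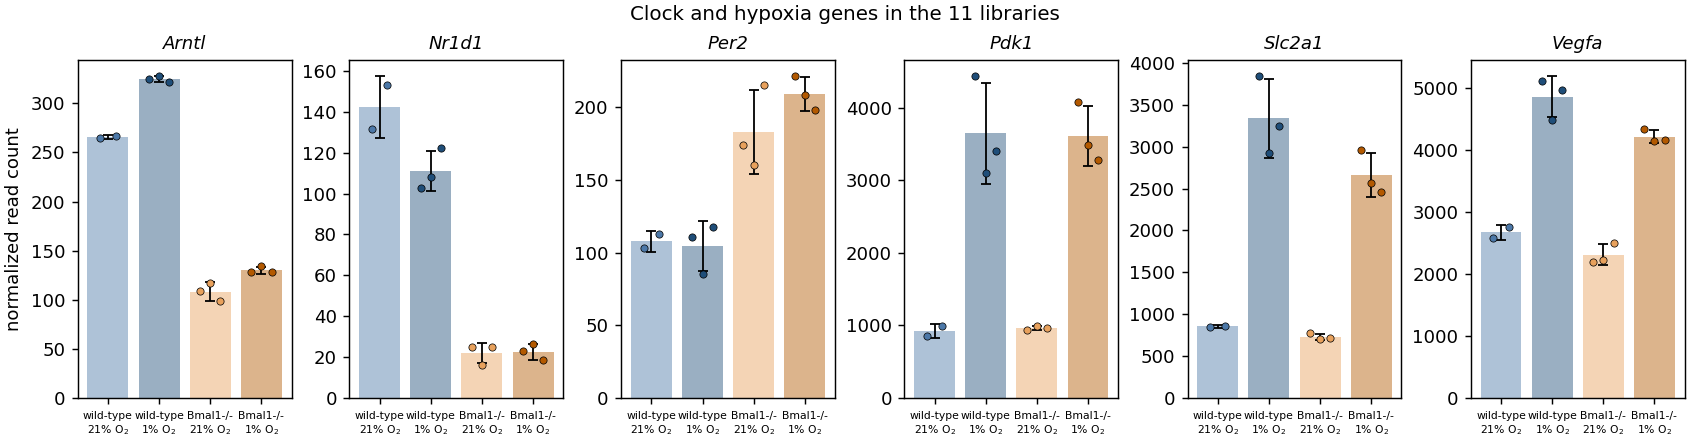
Normalized read counts of Arntl, Nr1d1, Per2, Pdk1, Slc2a1 and Vegfa in each of the 11 libraries, by genotype and oxygen level. Points are libraries, bars the group means and error bars the SD. Arntl was 98.8 to 134 in the knockout libraries and 264 to 328 in the wild-type libraries, and Pdk1, Slc2a1 and Vegfa were higher in hypoxia in both genotypes.

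Whether loss of Bmal1 altered the response to low oxygen was tested as the difference between the 2 hypoxia effects. Hypoxia genes such as Vegfa, Slc2a1, Pdk1 and Ldha rose in both genotypes, and no difference between the genotypes was shown for them. For Vegfa the difference, knockout minus wild-type, was 0.01 on the log2 scale (SE 0.09, adjusted p = 0.995), for Slc2a1 -0.10 (SE 0.13, adjusted p = 0.949), for Pdk1 -0.07 (SE 0.17, adjusted p = 0.97) and for Ldha -0.10 (SE 0.06, adjusted p = 0.917). Kdm3a had -0.30 (SE 0.08, adjusted p = 0.727) and Bhlhe40 0.57 (SE 0.17, adjusted p = 0.871), and neither passed. When adjusted over the list alone, 0 of the 32 HIF targets were called upward and 2 downward for this difference. For glycolysis 0 were called in either direction. Averaged over the 21 glycolysis genes, hypoxia raised the mean log2 level by 0.92 in wild-type and 0.90 in knockout cells, a difference of -0.01 (SE 0.13, exact permutation p = 0.93, two-sided, adjusted 0.93). Over the 32 HIF targets the rises were 1.36 and 1.28, a difference of -0.08 (SE 0.14, exact permutation p = 0.69, adjusted 0.93). A score over 1097 genes called for the mean hypoxia effect, 720 upward and 377 downward, differed by 0.02 (SE 0.05, exact permutation p = 0.8, adjusted 0.93). Those genes were chosen on these libraries, so the size of that score is not independent evidence. These 3 tests permuted the genotype labels within oxygen levels in 200 arrangements, the smallest p they can give being 0.005. A simulated score shifted in the knockout hypoxia libraries alone reached an exact permutation p of only 0.1, so the tests could miss such a difference. A genotype difference present at both oxygen levels also widens the permuted differences and can raise p. The HIF target score had means of 8.66 in wild-type and 8.48 in knockout normoxia, and 10.02 and 9.76 in hypoxia. Without wild-type normoxia replicate 1 the genes called for the mean hypoxia effect were chosen again on the libraries left, and their score differed by -0.14. That value therefore does not belong to the same 1097 genes.

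Among single genes, the limma fit called 1 gene upward and 0 downward for this difference, with 784 at an unadjusted p under 0.05. The edgeR test called 0 in either direction (777 unadjusted) and DESeq2 called 4 upward and 0 downward (523 unadjusted). In simulated data, limma called 41.8% of genes given a log2 shift of 0.5 in knockout hypoxia alone, and 88.1% of those given a shift of 1. The shifted genes had a mean of at least 50, so these shares do not cover lower genes. With 200 genes shifted at once, the Benjamini-Hochberg adjustment is easier to pass than where few genes differ. The shares may therefore overstate what the fit could find for this difference. The called gene was the small nucleolar RNA gene Gm23925 (ENSMUSG00000064405), singled out after its values were seen. The count upward became 2 without wild-type normoxia replicate 2 or knockout normoxia replicate 3. The count downward became 1 without wild-type normoxia replicate 1 or 2, wild-type hypoxia replicate 3 or knockout hypoxia replicate 2. Of the gene lists, glycolysis had camera adjusted p = 0.256 and HIF targets 0.134, both with a downward sign. These became 0.00165 and 0.000574 without wild-type hypoxia replicate 2, and 0.0114 and 0.00293 without knockout hypoxia replicate 1. Of the 251 genes that rose in wild-type hypoxia, 200 also rose in knockout hypoxia, where 7.91 would be shared by independent lists, and of the 69 that fell 38 also fell (0.646 by independent lists). No gene was called in opposite directions (0 of each). The comparisons share no libraries, but they share the variance estimate of each gene, which came from all 11 libraries. The numbers for independent lists may therefore be too low.

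**Figure D2:**
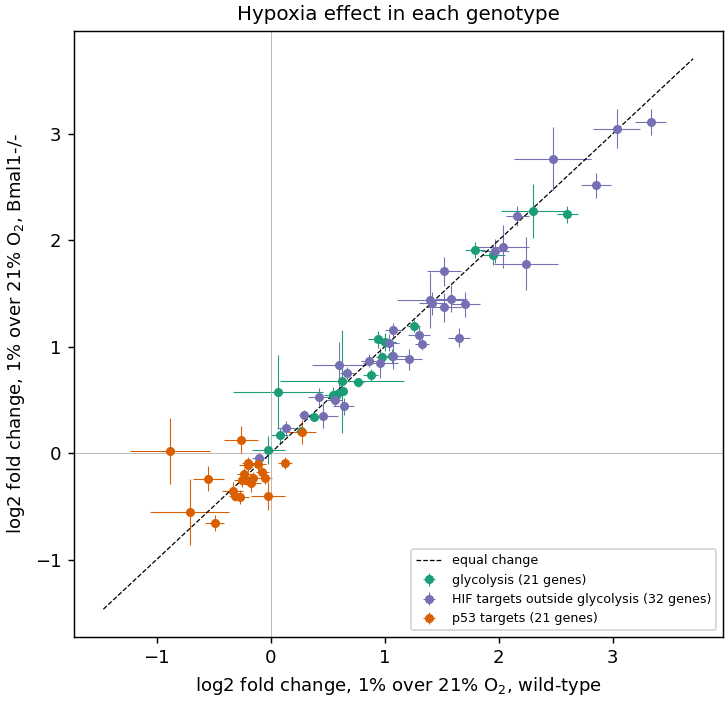
Log2 change in hypoxia in wild-type cells (x axis) against knockout cells (y axis) for the 21 glycolysis genes, 32 HIF targets and 21 p53 targets. Points are genes, error bars the SE of each change, and the dashed line marks equal change. The HIF targets have medians of 1.31 and 1.09 and the p53 targets of -0.21 and -0.24.

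The genotype comparison in normoxia asked how loss of Bmal1 changed myoblasts at 21% oxygen. Of the clock genes, Nr1d1 and Nr1d2, which CLOCK and BMAL1 activate through the E-box, were among the named genes that fell by the largest amounts. Nr1d2 (chromosome 14, 18204054 to 18239127), which encodes the repressor REV-ERB beta, fell from 1246 ± 4.46 (SD, n = 2) to 136 ± 4.18 (SD, n = 3) normalized counts, and Nr1d1, REV-ERB alpha, from 142 ± 15 (SD, n = 2) to 22.0 ± 5.0 (SD, n = 3). Cry1, a clock repressor that REV-ERB proteins hold down, rose from 275 ± 23.4 (SD, n = 2) to 819 ± 26.9 (SD, n = 3). Bhlhe40 fell by 1.66 (SE 0.13) and Per2, a period gene, rose by 0.75 (SE 0.16), a call lost without wild-type normoxia replicate 1 (adjusted p = 0.0762). Dbp, another E-box target, did not pass (-0.34, adjusted p = 0.415). Of the 14 clock repressors and E-box outputs 3 rose and 4 fell (3 and 5 when adjusted over the list alone), so the list had no single direction (camera adjusted p = 0.308). The list of 10 clock activators and RORE outputs includes genes that REV-ERB proteins repress. In it 3 rose, among them Nfil3 (0.63, SE 0.09), and 2 fell, Arntl among them. The same counts were called when adjusted over the list alone (camera adjusted p = 0.761).

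Genes of fibroblasts and extracellular matrix were lower in knockout cells. Of 10 tested markers of fibro-adipogenic progenitors and fibroblasts, the connective tissue cells of muscle, 0 rose and 9 fell in normoxia, with 10 fallen when adjusted over the list alone (median -0.74, camera adjusted p = 7.87e-15, and adjusted p = 0.00179 with an estimated correlation). The fixed list held 14 markers. Dpt, Pi16 and Dpp4 were below the filter and Tcf21 was absent from the values, so these were not tested. Pdgfra, the receptor that marks these progenitors, fell from 693 ± 10.8 (SD, n = 2) to 266 ± 13.2 (SD, n = 3). The basement membrane collagen Col15a1 fell from 2319 ± 101 (SD, n = 2) to 916 ± 58.0 (SD, n = 3). Markers of pericytes and smooth muscle had 0 risen and 6 fallen of 10 (1 risen and 7 fallen when adjusted over the list alone, median -0.57, camera adjusted p = 1.24e-05, and adjusted p = 0.0238 with an estimated correlation), such as Pdgfrb (-1.40, SE 0.09) and Cspg4 (-1.41, SE 0.13). Extracellular matrix genes had 3 risen and 17 fallen of 30, with 4 and 22 when adjusted over the list alone (median -0.33, camera adjusted p = 9.05e-16, and adjusted p = 0.0547 with an estimated correlation). The matricellular gene Ccn2 fell by 1.62 (SE 0.08), the collagen cross-linker Loxl2 by 1.49 (SE 0.09) and the protease inhibitor Timp3 by 1.53 (SE 0.11). Inflammatory cytokine and chemokine genes had 0 risen and 6 fallen of 14 (1 and 8 when adjusted over the list alone, median -0.48, camera adjusted p = 0.000202, and adjusted p = 0.0547 with an estimated correlation), among them the monocyte attractant Ccl2 (-1.13, SE 0.11) and the cyclooxygenase Ptgs2 (-1.19, SE 0.10). Immediate early genes had 0 risen and 7 fallen of 18 (8 fallen when adjusted over the list alone, median -0.30, camera adjusted p = 4.12e-05, and adjusted p = 0.243 with an estimated correlation), with Egr2 at -1.36 (SE 0.11).

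Genes of muscle differentiation were higher in knockout cells. In normoxia 18 of 31 rose and 0 fell, with 25 risen when adjusted over the list alone (median 0.44, camera adjusted p = 9.05e-16, and adjusted p = 0.259 with an estimated correlation). The embryonic myosin Myh3 rose from 7316 ± 975 (SD, n = 2) to 11380 ± 941 (SD, n = 3), and the slow troponin Tnnt1 from 2201 ± 13.8 (SD, n = 2) to 3232 ± 159 (SD, n = 3). These genes moved beside the fall of fibroblast markers (median -0.74) and pericyte markers (median -0.57) in the same libraries. Of the 17 satellite cell and myoblast identity genes, 1 rose and 2 fell (2 and 4 when adjusted over the list alone, camera adjusted p = 0.313). The myogenic factor Myf5 rose by 0.59 (SE 0.08), while Myod1 (-0.13, adjusted p = 0.221) and Pax7 (-0.20, adjusted p = 0.249) did not pass. Cell cycle genes stood slightly higher. The mitosis list had 6 risen and 0 fallen of 30 (11 risen when adjusted over the list alone, median 0.10, camera adjusted p = 1.24e-05, and adjusted p = 0.259 with an estimated correlation), among them Top2a, the topoisomerase of dividing cells, at 0.25 (SE 0.05). The DNA replication list had 4 risen and 0 fallen of 30 (9 risen when adjusted over the list alone, median 0.13, camera adjusted p = 1.03e-05, and adjusted p = 0.259 with an estimated correlation).

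Other large differences in normoxia were falls in Aldh1a2, which makes retinoic acid, from 738 ± 10.8 (SD, n = 2) to 151 ± 11.4 (SD, n = 3), in the chemokine Cxcl14 (-2.53, SE 0.15) and in the growth factor Hgf (-2.52, SE 0.21). With pseudogenes and predicted models set aside, the largest rises included Plekha7, an adherens junction gene, at 3.21 (SE 0.21) and Asb4 at 3.18 (SE 0.30). Plekha7 (chromosome 7, 116123485 to 116308376) lies within 10 Mb of Arntl. HIF targets had 2 risen and 7 fallen of 32 (4 and 8 when adjusted over the list alone, median -0.15, camera adjusted p = 0.0201, and adjusted p = 0.581 with an estimated correlation), and the list's call was lost without wild-type normoxia replicate 1 (0.0686). The fallen included Lox (-0.63, SE 0.05), which cross-links collagen and is also in the list of fibroblast markers, lower in the same libraries (median -0.74). Vegfa (-0.21, SE 0.07, adjusted p = 0.0658), Slc2a1 (-0.22, SE 0.10, adjusted p = 0.196) and Hif1a (-0.03, adjusted p = 0.841) did not pass. In all, 506 genes rose and 833 fell in knockout cells in normoxia, 67 and 193 of them by at least 2-fold. The counts were 246 and 532 without wild-type normoxia replicate 1 and 229 and 439 without replicate 2, and 312 rose without knockout normoxia replicate 2.

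The genotype comparison in hypoxia asked how the genotypes differed after 6 h at 1% oxygen. Nr1d2 stood at 128 ± 14.1 (SD, n = 3) in knockout against 1131 ± 50.1 (SD, n = 3) in wild-type cells, Nr1d1 at 22.7 ± 3.98 (SD, n = 3) against 111 ± 9.86 (SD, n = 3), Cry1 at 929 ± 49.7 (SD, n = 3) against 278 ± 3.17 (SD, n = 3) and Per2 at 209 ± 11.7 (SD, n = 3) against 104 ± 17.0 (SD, n = 3). Clock repressors and E-box outputs had 4 risen and 4 fallen of 14, with the same counts when adjusted over the list alone (camera adjusted p = 0.729). Clock activators and RORE outputs had 1 risen and 2 fallen of 10, with 4 and 2 when adjusted over the list alone (camera adjusted p = 0.771). Fibroblast markers again had 0 risen and 9 fallen of 10, with 10 fallen when adjusted over the list alone (median -0.72, camera adjusted p = 2.55e-16, and adjusted p = 0.00125 with an estimated correlation). Pdgfra stood at 306 ± 17.6 (SD, n = 3) in knockout and 749 ± 34.8 (SD, n = 3) in wild-type cells. Pericyte and smooth muscle markers had 0 risen and 7 fallen of 10 (1 and 7 when adjusted over the list alone, median -0.67, camera adjusted p = 1.71e-07, and adjusted p = 0.00878 with an estimated correlation). Extracellular matrix genes had 4 risen and 17 fallen of 30 (4 and 20 when adjusted over the list alone, median -0.30, camera adjusted p = 7.48e-12, and adjusted p = 0.0903 with an estimated correlation), Ccn2 at -1.61 (SE 0.07) and Timp3 at -1.54 (SE 0.10) among the fallen. Muscle differentiation genes had 22 risen and 0 fallen of 31 (27 and 1 when adjusted over the list alone, median 0.42, camera adjusted p = 3.52e-20, and adjusted p = 0.206 with an estimated correlation). The giant sarcomere protein gene Ttn stood at 19872 ± 1210 (SD, n = 3) in knockout against 10805 ± 880 (SD, n = 3) in wild-type cells. Inflammatory genes had 0 risen and 7 fallen of 14 (8 fallen when adjusted over the list alone, median -0.49, camera adjusted p = 1.5e-06, and adjusted p = 0.0196 with an estimated correlation). Immediate early genes had 0 risen and 4 fallen of 18 (8 fallen when adjusted over the list alone, camera adjusted p = 0.000158, and adjusted p = 0.238 with an estimated correlation).

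HIF targets stood lower in knockout than in wild-type cells in hypoxia, with 0 risen and 9 fallen of 32 (1 and 11 when adjusted over the list alone, median -0.21, camera adjusted p = 1.94e-06, and adjusted p = 0.343 with an estimated correlation). They included Ddit4, an inhibitor of mTORC1 signalling (-0.62, SE 0.11), and Lox (-0.57, SE 0.04), which is also a fibroblast marker. Fibroblast markers (median -0.72) and pericyte markers (median -0.67) were lower in the same libraries. Vegfa was lower by a small amount, 4218 ± 106 (SD, n = 3) against 4866 ± 329 (SD, n = 3), with log2 difference -0.20 (adjusted p = 0.0483), and Slc2a1 by -0.32 (adjusted p = 0.0392). The Vegfa call was lost when any of 8 single libraries was left out (adjusted p = 0.0537 to 0.18), all but knockout normoxia replicates 1 and 3 and wild-type hypoxia replicate 2. The Slc2a1 call was lost with any of 6 (0.0512 to 0.155), wild-type normoxia replicates 1 and 2, wild-type hypoxia replicates 1 and 3 and knockout hypoxia replicates 2 and 3. Hif1a (-0.07, SE 0.05, adjusted p = 0.526), Pdk1 (-0.003, SE 0.11, adjusted p = 0.993) and Ldha (0.01, SE 0.04, adjusted p = 0.933) did not pass. Glycolysis genes had 0 risen and 2 fallen of 21, with 3 fallen when adjusted over the list alone (camera adjusted p = 0.134). That value became 0.00187 without wild-type hypoxia replicate 2 and 0.00792 without knockout hypoxia replicate 1. In all, 491 genes rose and 827 fell, 54 and 174 of them by at least 2-fold. The count risen was 325 without wild-type hypoxia replicate 2 and 318 without knockout hypoxia replicate 2. Of the genes risen in normoxia 247 also rose in hypoxia (16.9 by independent lists), and of those fallen 571 also fell (46.8 by independent lists). In the opposite direction 1 risen and 1 fallen gene were called. These comparisons, too, share the variance estimate of each gene, so the numbers for independent lists may be too low.

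**Figure D3:**
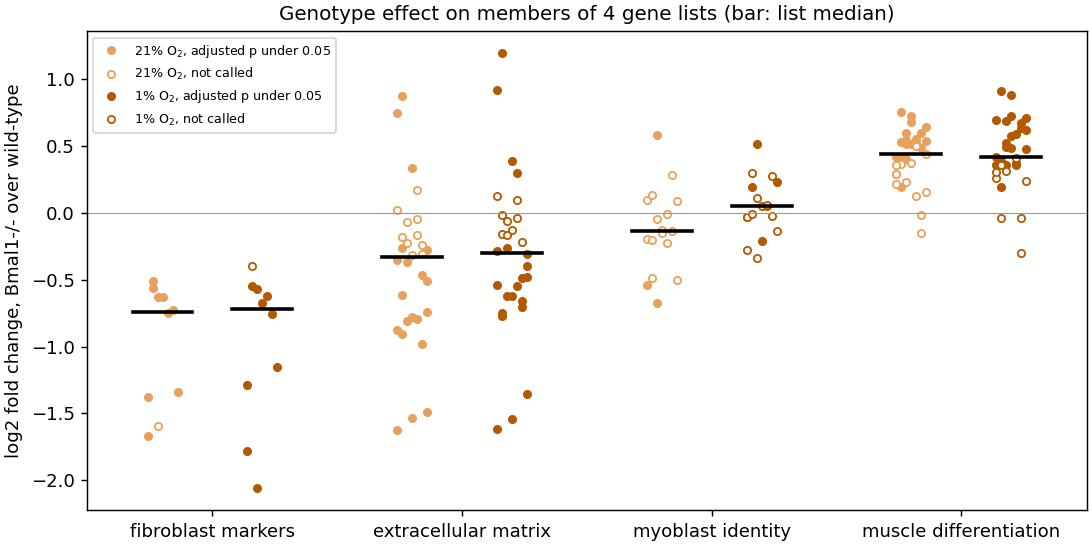
Log2 difference between knockout and wild-type cells for each tested member of 4 gene lists, fibroblast markers, extracellular matrix, myoblast identity and muscle differentiation, in normoxia and in hypoxia. Filled points passed an adjusted p of 0.05 and the bar marks the list median, -0.74 and -0.72 for the fibroblast markers and 0.44 and 0.42 for muscle differentiation.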

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

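The tests of the histone list itself, of S phase and of short transcripts were chosen after the result was seen. Each result below stands out because the hypoxia effect differed between wild-type and knockout cells in a test of that difference.

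Gm23925 (ENSMUSG00000064405), a small nucleolar RNA gene on chromosome 2 (158359798 to 158359929), was chosen after its values were seen, and its difference had adjusted p = 0.00368 in limma. Its normalized counts were 37.5 and 35.4 in wild-type normoxia, 44.8, 34.4 and 26.4 in wild-type hypoxia, 0, 0 and 0 in knockout normoxia, and 31.0, 28.2 and 16.4 in knockout hypoxia. The fitted difference, 4.74 (SE 0.50) on the log2 scale, rests on a group at 0 and bounds no fold. The call was lost with a pseudocount of 10 and with edgeR (0 risen each), and the gene is not tested under the stricter filter, which needs at least 50 in 2 libraries. DESeq2 called it (adjusted p = 0.00204). The symbol is shared by 2 identifiers, and the assignment of reads between them was not tested.

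Among the lists, satellite cell and myoblast identity had a higher hypoxia effect in knockout cells (camera adjusted p = 0.0122, median 0.15, 13 of 17 genes higher, 0 called by limma). The same held for extracellular matrix (adjusted p = 0.000471, median 0.12, 25 of 30 genes higher, 0 called by limma). Cytosolic ribosomal proteins had a lower effect (adjusted p = 3.49e-05, median -0.05, 67 of 79 genes lower, 0 called by limma). With an estimated correlation none passed (adjusted p = 0.781, 0.781 and 0.837 in that order). Without wild-type normoxia replicate 2 the values were 0.37, 0.37 and 0.401, and the identity list also missed the threshold without knockout normoxia replicate 2 (0.0513) or wild-type hypoxia replicate 2 (0.105). All 14729 genes held 784 at an unadjusted p under 0.05 for this difference, with 0 called by edgeR and 4 by DESeq2.

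Histone genes of the replication-dependent clusters, a list of 62 formed after the values were seen, had 38 risen and 0 fallen with hypoxia in knockout cells (mean 0.41, SE 0.07) and had 0 called in wild-type cells by limma (mean 0.08, SE 0.08). The difference was 0.32 (SE 0.10, exact permutation p = 0.03, two-sided), higher in 58 of 62 genes, with camera p = 0.0212 at an estimated correlation. For single histone genes limma and edgeR called 0 for this difference, and DESeq2 called Hist1h2ac (adjusted p = 0.00617) and Hist1h2ah (adjusted p = 0.038), which are named after their values were seen. Without wild-type normoxia replicate 1 it was 0.22 (exact permutation p = 0.138), and without knockout normoxia replicate 1 or 2 it was 0.31 or 0.29 (exact permutation p = 0.05 each). The mean of the DNA replication list changed by 0.0142 (SE 0.0279) in knockout hypoxia. This argues against a larger share of cells in S phase only if these genes follow S phase about as closely as histone genes. That was not tested. Better recovery of RNA without a poly(A) tail is not decided by snRNA and snoRNA genes. Their median difference was -0.152 and their mean -0.163 (SE 0.19 across libraries), too wide a spread to exclude a rise smaller than that of the histone genes. Better recovery of short transcripts is argued against by short protein-coding genes, with a median of -0.0306 and a mean of 0.0295 (SE 0.0206 across libraries). Between genotypes the list had 2 risen and 3 fallen in normoxia (mean -0.08, SE 0.08) and 28 risen and 0 fallen in hypoxia (mean 0.24, SE 0.07, camera p = 0.0658 at an estimated correlation). Hist1h2ah was called lower in knockout normoxia (-0.83, adjusted p = 0.0219) and did not pass in hypoxia (0.47, adjusted p = 0.161), whereas Hist1h2ac did not pass in normoxia (-0.26, adjusted p = 0.0666) and was called higher in hypoxia (0.32, adjusted p = 0.0141). A genotype difference in the hypoxia effect on histone RNA stays open as a hypothesis, found and tested on the same libraries, and at which oxygen level it arises is open too.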

How the results depend on the processing

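Thinned reads and counts without pseudogenes and genes near Arntl were alternatives chosen after seeing the data. Requiring a 2-fold change gave 74 risen and 7 fallen genes in wild-type hypoxia, 84 and 6 in knockout hypoxia, 67 and 193 between genotypes in normoxia and 54 and 174 in hypoxia, fewer by construction. Without the variance trend 32 fell in wild-type hypoxia, 288 rose and 63 fell in knockout hypoxia and 319 rose between genotypes in normoxia. With only the groups compared, which leaves fewer libraries, 35 fell in wild-type hypoxia and 294 rose and 555 fell between genotypes in normoxia. For the difference of hypoxia effects, 0 rose with a pseudocount of 10, 0 with the stricter filter, 0 with edgeR and 4 with DESeq2. At an adjusted p under 0.01 the hypoxia effects shared 128 risen and 11 fallen genes. With an estimated correlation muscle differentiation had adjusted p = 0.259 in normoxia and 0.206 in hypoxia, and extracellular matrix 0.0547 and 0.0903. Clock activators and RORE outputs changed direction with fry (0.00581 in normoxia, 0.00129 in hypoxia), which tests the list's own genes and not the list against others. The score of genes called for the mean hypoxia effect changed sign without wild-type normoxia replicate 1 (-0.142). Its genes were chosen again on the libraries left, so the set was not the same. Except where construction is named, the cause was not tested. Leaving out each library gave 143 to 248 risen and 18 to 72 fallen in wild-type hypoxia, 303 to 479 and 64 to 156 in knockout hypoxia, 1 to 2 and 0 to 1 for their difference, 229 to 530 and 439 to 835 between genotypes in normoxia, and 318 to 497 and 598 to 846 in hypoxia. A lone wild-type normoxia library was then assumed to vary like the other groups. Glycolysis and HIF targets ranged from 1.72e-51 to 1.14e-40 and 5.73e-73 to 2.08e-61 in wild-type hypoxia, 2.56e-44 to 3.65e-38 and 2.45e-63 to 1.77e-51 in knockout hypoxia, and 0.00165 to 0.984 and 0.000574 to 0.984 for the difference. Genotype ranges in normoxia and hypoxia were 1.97e-21 to 5.29e-09 and 2.7e-28 to 7.73e-17 for muscle differentiation, 7.28e-19 to 2.49e-12 and 1.47e-12 to 2.99e-10 for extracellular matrix, and 3.98e-15 to 8.81e-13 and 6.86e-17 to 2.05e-15 for fibroblast markers. Scores ranged from -0.086 to 0.0575 for glycolysis and -0.161 to 0.0145 for HIF targets. For genes called for the mean hypoxia effect, chosen again each time, the range was -0.142 to 0.10. The histone difference ranged from 0.22 to 0.426. Reads thinned to the smallest library gave 246 and 66, 430 and 113, 1 and 0, 449 and 742, and 451 and 768 risen and fallen genes in the same order, so unequal depth moved no count by over 1.5 times. Without pseudogenes and genes near Arntl the genotype counts were 507 and 833 in normoxia and 488 and 825 in hypoxia. Over all alternatives, 14626 values of named genes kept their side of the threshold, 589 lost a call and 141 gained one. With a call in either setting, 0 changed direction. A change of direction between uncalled values was not counted.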

Other observations

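The tests of pseudogenes, of genes near Arntl, of fibroblast-like cells and of the share of non-myogenic cells were chosen after the result was seen. In wild-type hypoxia, ER chaperones had 1 risen and 0 fallen of 20 (camera adjusted p = 0.00504, 0.231 with an estimated correlation, 0.0878 without wild-type normoxia replicate 2). The integrated stress response had 1 risen and 1 fallen of 24 (0.0261, 0.496 with an estimated correlation, 0.0998 without wild-type normoxia replicate 1 and 0.188 without wild-type hypoxia replicate 3). Muscle differentiation had 0 risen and 1 fallen of 31 (0.00496, 0.666 with an estimated correlation, 0.859 without wild-type normoxia replicate 2 and 0.363 without wild-type hypoxia replicate 2). In knockout hypoxia the nuclear-encoded respiratory chain had 0 called of 48 (0.000266, 0.463 with an estimated correlation, median -0.05) and NRF2 and pentose phosphate genes had 1 risen and 4 fallen of 22 (0.0028, 0.43 with an estimated correlation). Muscle differentiation (0.0381), TCA cycle (0.042) and cytosolic ribosomal proteins (0.0221) passed there too, with 0.742, 0.213 and 0.747 with an estimated correlation. Each lost its call without any 1 of 4 libraries. These were knockout normoxia replicates 1 and 3 and knockout hypoxia replicates 2 and 3 for differentiation (0.0702 to 0.415), knockout normoxia replicate 1, wild-type hypoxia replicate 1 and knockout hypoxia replicates 2 and 3 for the TCA cycle (0.0503 to 0.185), and knockout normoxia replicates 1 and 2 and knockout hypoxia replicates 2 and 3 for ribosomal proteins (0.0841 to 0.234).

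Between genotypes in normoxia the respiratory chain (camera adjusted p = 0.0019, median 0.07), the integrated stress response (0.0113, and 0.0596 without knockout normoxia replicate 3) and ribosomal proteins (2.16e-05) stood higher, with 0.581, 0.558 and 0.581 with an estimated correlation. The call of the ribosomal proteins was lost without wild-type normoxia replicate 2. Of these 79 genes 0 rose and 1 fell, Rps13 (-0.48), and the list median was 0.06. In hypoxia the integrated stress response stood higher (0.000598, 0.304 with an estimated correlation) and NRF2 genes lower (0.000681, 0.359 with an estimated correlation), while mitosis (3 risen of 30, 9.9e-06) and DNA replication (5 risen of 30, 1e-05) stood higher, with 0.238 and 0.251 with an estimated correlation. Among the lists that missed the camera threshold in both genotype comparisons were NAD metabolism (0.424 and 0.844), mitochondrially encoded transcripts (0.132 and 0.253), TCA cycle (0.173 and 0.211), ER chaperones (0.777 and 0.131), cholesterol synthesis (0.605 and 0.453), interferon response (0.241 and 0.0595), p53 targets (0.522 and 0.839), oxygen sensing (0.559 and 0.667), endothelial markers (0.424 and 0.0724) and Schwann cell markers (0.235 and 0.742). In hypoxia, leaving out 1 library brought 3 of the lists just named past the threshold. They were the mitochondrially encoded transcripts without wild-type hypoxia replicate 3 (0.0247), the interferon response without wild-type hypoxia replicate 2 or 3 or knockout hypoxia replicate 2 (0.0458, 0.0311 and 0.0244), and the endothelial markers without wild-type hypoxia replicate 1 (0.0481). For the difference between the hypoxia effects, clock repressors and E-box outputs had camera adjusted p = 0.0526 (median 0.20, 10 of 14 genes higher in knockout cells). That list passed without wild-type normoxia replicate 1 (0.0337), knockout normoxia replicate 3 (0.0144), wild-type hypoxia replicate 1 (0.0122) or 3 (0.0475), or knockout hypoxia replicate 1 (0.0181) or 3 (0.028). Its adjusted p was 0.781 with an estimated correlation. ER chaperones had the same camera adjusted p for this difference (0.0526, median -0.05, 16 of 20 genes lower, 0.781 with an estimated correlation). They too passed without some single libraries, such as wild-type hypoxia replicate 3 (0.0238). So did other lists, among them the respiratory chain without wild-type hypoxia replicate 3 (0.00635) and muscle differentiation without wild-type hypoxia replicate 1 (0.00194). Of the untested lists, in the genotype comparisons by limma, leukocyte markers had 0 of 3 called, the adipocyte marker Pparg fell at both oxygen levels, sex-linked transcripts had 0 of 4 called, and chromosome 7 neighbours had 1 risen and 2 fallen of 23 in normoxia and 1 and 1 in hypoxia. The Pparg call in normoxia rested on both wild-type normoxia libraries. Its call in hypoxia was lost without wild-type hypoxia replicate 3 or knockout hypoxia replicate 2 (adjusted p = 0.0652 to 0.07). For the hypoxia effect in knockout cells 1 of the 4 sex-linked transcripts fell, Kdm5d. Its call was lost without any 1 of 5 libraries (adjusted p = 0.0507 to 0.133), knockout normoxia replicates 2 and 3 and knockout hypoxia replicates 1, 2 and 3.

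Ribosomal protein pseudogenes changed with genotype by amounts that their parent genes did not. Rps13-ps1 had 69.8 ± 6.29 (SD, n = 2) normalized counts in wild-type and 3109 ± 209 (SD, n = 3) in knockout normoxia, Rps13-ps2 had 144 ± 17.7 (SD, n = 2) and 0, and Rps13 itself 7115 ± 112 (SD, n = 2) and 5101 ± 332 (SD, n = 3). Rps15a, the parent of the other pseudogenes concerned, had 8833 ± 199 (SD, n = 2) and 8941 ± 554 (SD, n = 3) and did not pass (0.02, SE 0.05, adjusted p = 0.895). These genes were chosen after their values were seen. Of 67 tested pseudogenes with a known parent, 6 had a genotype call of at least 4-fold, and all 6 had a parent within 10 Mb of Arntl, against 1 of the other 61 (two-sided Fisher's exact test p = 7.01e-08, on calls in either direction). Only the parents Rps13 and Rps15a are involved, so the 6 are not independent. Summed over each family, the genotype difference in normoxia was 0.16 for Rps13 and 0.29 for Rps15a. A candidate explanation is that reads of parents near Arntl were assigned to their pseudogenes, differently in the genotypes. Assignment in knockout libraries alone would not lower Rps13-ps2, which is among the 6. Rps13 lost fewer reads than Rps13-ps1 gained and Rps15a did not pass, so the source of the added reads stays open in part for the Rps13 family and in whole for the Rps15a family. Sequence was not analysed here. A wider interval from another strain around Arntl cannot be told apart from its absence by the share of genes called, 20 of 120 within 10 Mb (16.7%) against 1811 of 14498 elsewhere (12.5%, two-sided Fisher's exact test p = 0.166, odds ratio 1.4, 95% interval 0.819 to 2.29).

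Lower fibroblast and matrix genes in knockout libraries might reflect fewer fibroblast-like cells or lower expression per cell. All 10 tested fibroblast markers were lower at both oxygen levels, from -1.67 to -0.51 in normoxia. The other markers of the list, Dpt, Pi16, Dpp4 and Tcf21, were below the filter or absent from the values. Of the 10, 6 lay within 2 SE of the list median, so fewer cells cannot be told apart from a change within cells. Higher muscle differentiation genes might reflect a lower share of non-myogenic cells or a change within cells. A lower share alone would raise differentiation and identity genes alike if both were confined to myogenic cells. Their list means differed by 0.54 (SE 0.06) in normoxia and 0.40 (SE 0.05) in hypoxia, so the lists did not rise alike. Whether the identity genes are confined to myogenic cells was not tested, so these values do not decide between the explanations.

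For the hypoxia effect in knockout cells, fitted on its 6 libraries, the real split called 521 genes and the highest other split 1, with 1 of 10 splits calling as many. For the genotype effect in hypoxia the real split called 1268 and the highest other 2, with 1 of 10 splits calling as many. A total of 10 splits is too few for a share under 0.05. Every other split mixed libraries of both real groups on each side, which widens the spread and makes few calls likely in advance. The splits therefore do not measure how many genes chance would call.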
